A study of Mus musculus with 32 samples.

How the data were processed

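Total RNA from 4 mouse macrophage lines was measured on 32 Affymetrix Mouse Gene 1.0 ST arrays, 1 colour with biotin label, 1 array per RNA preparation. The lines, on an M-/- background in the labels, are named after the CSF-1 receptor (CSF-1R) they express: WT and 3ABY721 have the phosphorylated Tyr-721, and Y721F and 3AB lack that tyrosine, per the series' design text. Cells were kept in α-MEM with newborn calf serum and human CSF-1 at 120 ng/mL, and RNA was taken with Trizol, per the labels' protocols; preparations with an RNA integrity number above 9.5 were used, per the series' design text. The 16 groups hold 2 arrays each, numbered I and II in the labels and called biological replicates in the series' design text. In the time course, WT and Y721F cells starved of CSF-1 overnight were given CSF-1 for 0, 20, 60 or 180 min (16 arrays). In the steady-state experiment, the 4 lines were starved or grown continuously in CSF-1 (16 arrays).

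The authors deposited log2 signals per probe set for 35556 probe sets, with array medians between 5.97 and 6.22. That the values are on the log2 scale was read from the values, since the sources used here do not state a unit. Array quartiles lie close together but not identical, so the arrays had been normalized. The background correction, summarization, normalization method and genome build are not given in the sources used here. The series' design text names limma and a cutoff of a fold above 1.5 with p under 0.05.

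Probe sets were paired with genes by the array's annotation table, which lists 23410 of them. Of these, 21789 name 1 gene and were used, 1621 name several genes and were left out, and 12146 probe sets have no entry. Gene identifiers of 21698 probe sets matched the current mouse gene table, which changed 0 symbols. Where a gene had several probe sets (999 genes), the one with the highest mean over the 32 arrays stood for it, which left 19938 genes. Mir21a is not among the genes named by a single-gene probe set and was not analysed here.

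The 8 groups of each experiment were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a mean per group, 8 residual degrees of freedom and a prior of 3.48 (time course) or 6.33 (steady state). Every p of a single gene comes from limma, with Benjamini-Hochberg adjustment over 19938 genes within each of 19 comparisons. A gene is called where its adjusted p is under 0.05 and its fold is above 1.5, and "rose", "fell", "higher" and "lower" are used for single genes in that sense. Differences are log2 with their standard error (SE), each from 2 arrays per group, and the number of arrays limits the precision. The difference of 2 responses was tested as its own contrast. Genes shared by separate comparisons were set against the product of both counts divided by 19938 and a hypergeometric p per direction; genes are not independent, so that p is a description.

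Before the data were examined, the comparisons, thresholds, 23 gene lists (411 genes, of which 387 were measured), the alternatives and the rule for named genes were fixed. The lists cover immediate early genes, ERK pathway feedback, inflammatory cytokines and chemokines, NF-κB feedback, classical (M1) and alternative (M2) activation markers, type I interferon response, MHC class II, G1/S and DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis, LXR targets, glycolysis, FOXO targets, the integrated stress and unfolded protein response, reported miR-21 targets and macrophage identity. Cell type lists cover dendritic cells, osteoclasts, granulocytes and mast cells, fibroblasts and lymphocytes. Each list was tested against the other genes with limma's camera at its preset correlation of 0.01, adjusted over the 23 lists of a comparison, and again with a correlation estimated from the residuals.

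Named genes are called genes whose 2 arrays of one group both lie above, or both below, those of the other. For the WT time course the 8 largest rises and 4 largest falls per time are named with their Y721F values, and for Y721F the 3 largest either way. For Y721F against WT at 0 min and for each difference of responses or growth effects they are the 5 largest either way. Genes shared by both pairs of lines are the 10 (grown) or 5 (starved) largest either way, each pair's own genes the 3 largest, and genes shared by the 4 lines grown against starved the 10 largest. For a list they are up to 4 called members with the largest change. The 20th percentile of signal, under which the size of a difference is read as a lower bound, was chosen after seeing the data. Csf1r, Pdcd4, Spry1, Spry2, Tnf, Il6, Il1b, Nos2, Il12b, Arg1, Mrc1, Il10, Cd163, Cd86, Ccnd1, Fos, Egr1 and Myc are given whatever their value.

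Whether arrays with the same number pair was checked from the correlation, across genes, of their deviations from the group means. Within the WT time course the 6 correlations of same-numbered arrays at different times lay between 0.487 and 0.734, and within Y721F between 0.353 and 0.648. Between the WT and Y721F time courses they lay between -0.063 and 0.290, and in the steady-state experiment they were not over 0.1 in every pair, within lines or between them. The numbers therefore pair arrays within each line of the time course, a pairing that comes from the values and not from a label, and a fit with the series number within each line as a block was added after this check. Other alternatives were the cutoff of the series text, all probe sets, leaving out genes below the 30th percentile of mean signal, quantile normalization, 1 fit of 32 arrays, the replicate number as a block, an intensity trend with robust variance, and leaving out each array in turn. In that last one the lone array of a group is assumed to vary like the other groups.

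The calling steps were tested on simulated arrays of 19938 genes with 100 genes changed 2-fold and 100 changed 4-fold. For WT at 60 min, 75% of the 2-fold and 94% of the 4-fold changes were recovered, with 8 wrong calls; for 3AB against 3ABY721 grown in CSF-1 these were 74%, 99% and 5. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.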

Results

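Gene expression was measured in 4 mouse macrophage lines, called WT, Y721F, 3ABY721 and 3AB below, which differ in the CSF-1 receptor they carry. CSF-1 is the growth factor on which these cells depend, and the receptor's Tyr-721 is present in WT and 3ABY721 and missing in Y721F and 3AB. Each receptor comes with its own line, so an effect of Tyr-721 cannot be told apart from other differences between the lines compared. WT and Y721F were starved and then given CSF-1 for 0, 20, 60 or 180 min, and the 4 lines were compared starved and grown in CSF-1. Each of the 16 groups has 2 arrays, and the paired arrays correlated across genes with Pearson r between 0.986 and 0.996. Array medians ran from 5.97 to 6.22 on the log2 scale. Csf1r, the receptor gene itself, read between 12.72 and 13.41 in the 32 arrays, so each line expressed it at a high level; a probe set does not read the mutated codon. Csf1r measured -0.57 (SE 0.12) in Y721F against WT grown in CSF-1, which is below the fold threshold although its adjusted p was 0.0067.

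The first question was how starved WT cells answer CSF-1. At 20 min the answer was a burst of immediate early transcription factors together with inflammatory messengers. Egr1, an early growth response factor, rose by 5.06 (SE 0.30, adjusted p = 1.58e-05), Nr4a1, an orphan nuclear receptor, by 4.61 (SE 0.34), with 2 arrays per group. Egr2 rose by 4.80 (SE 0.66) and the AP-1 subunits Fosb and Fos by 3.84 (SE 0.34) and 3.74 (SE 0.37). Ptgs2, which encodes the prostaglandin-forming enzyme COX-2, rose by 4.91 (SE 0.63), the cytokine gene Il1b by 3.76 (SE 0.43, adjusted p = 0.00375) and the monocyte chemoattractant Ccl2 by 3.60 (SE 0.52). The transcript C030016D13Rik was the 1 gene that fell, at -1.10 (SE 0.18, adjusted p = 0.0431). By limma, 32 genes changed, 31 of them up, and 86 with the series number within each line as a block. Of 26 immediate early genes, 12 rose and 21 when adjusted over the list alone (camera adjusted p = 3.3e-81). Of 24 inflammatory cytokines and chemokines, 3 rose, among them Cxcl2 at 3.40 (SE 0.47), and 8 adjusted over the list alone (camera adjusted p = 8.96e-14). Il1rn, the natural blocker of the IL-1 receptor and 1 of 23 M2 markers, rose by 1.51 (SE 0.17) (2 adjusted over the list alone, camera adjusted p = 0.000266). Of 19 M1 markers 3 rose, Ptgs2, Il1b and Socs3 (4 adjusted over the list alone, camera adjusted p = 8.65e-08). Socs3, a brake on cytokine signalling, rose by 3.06 (SE 0.42) and Nfkbiz by 1.99 (SE 0.25), 2 of 15 NF-κB feedback genes (2 adjusted over the list alone, 0.0036, and adjusted p = 0.33 with an estimated correlation). The ERK phosphatase gene Dusp5 rose by 2.29 (SE 0.35), 1 of 14 ERK feedback genes (3 adjusted over the list alone, 2.88e-07, and adjusted p = 0.0732 with an estimated correlation, or 0.0459 with the series block). Without 1 array the count was 12 (0 min I left out), 20 (0 min II), 16 (20 min I) or 17 (20 min II). Egr1, Nr4a1, Fosb, Fos, Il1rn and Rhob kept their calls each time, while Cxcl2, Socs3, Nfkbiz, Dusp5, Btg2, Ptgs2, Egr2, Ccl2 and C030016D13Rik lost theirs in at least 1 of these and Il1b without 0 min I or 20 min II (adjusted p = 0.0723 and 0.0518). C030016D13Rik also lost its call after quantile normalization (adjusted p = 0.0821).

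At 60 min immediate early genes were still up in WT, and ERK feedback, ribosome biogenesis and glycolysis genes leaned higher as lists that were not called with an estimated correlation. Of 26 immediate early genes 8 were called up (15 adjusted over the list alone, camera adjusted p = 1.95e-17, and adjusted p = 0.125 with an estimated correlation). Nr4a1 stayed high at 4.14 (SE 0.34) with 2 arrays per group, and Fosl1, a later AP-1 subunit, rose by 3.81 (SE 0.31, adjusted p = 0.000331), whereas Fos measured 0.28 (SE 0.37). Dusp5 rose by 3.14 (SE 0.35), the lipid droplet gene Hilpda by 2.98 (SE 0.39), the differentiation inhibitor Id1 by 3.08 (SE 0.52), Ptgs2 by 3.85 (SE 0.63), Ccl2 by 3.56 (SE 0.52) and Egr1 by 3.35 (SE 0.30). The M2 marker Arg1, which encodes the arginine-degrading enzyme arginase 1, rose by 2.39 (SE 0.31, adjusted p = 0.00457), and Il1b was still up at 2.41 (SE 0.43, adjusted p = 0.032). Falling genes were led by the lectin gene Clec2d at -1.76 (SE 0.32), the IL-10 receptor chain Il10ra at -1.72 (SE 0.29), the G-protein regulator Rgs2 at -1.48 (SE 0.24) and the transcriptional repressor Prdm1 (Blimp-1) at -1.48 (SE 0.20). By limma 126 genes changed in WT, 109 up and 17 down, and 745 with the series block. ERK feedback genes rose (4 of 14, 7 adjusted over the list alone, camera adjusted p = 2.56e-07, and adjusted p = 0.134 with an estimated correlation), with Phlda1 at 2.87 (SE 0.43), Dusp4 at 2.32 (SE 0.30) and Ets2 at 2.14 (SE 0.26) beside Dusp5. Ribosome biogenesis moved up as a list (1 of 23 called, the polyamine enzyme Odc1 at 2.15 (SE 0.36), 11 adjusted over the list alone, 1.12e-12, and adjusted p = 0.261 with an estimated correlation). That rise rests mostly on series I, whose list mean moved by 1.50 from 0 to 60 min and reached its 180 min level, against 0.22 in series II. Glycolysis did too, with the glucose transporter Slc2a1 at 2.0 (SE 0.33) (1 of 13, 2 adjusted over the list alone, 4.48e-06, and adjusted p = 0.157 with an estimated correlation). FOXO targets moved down, with the cell cycle inhibitor Cdkn1b at -1.13 (SE 0.21) and Bcl6 at -0.76 (SE 0.13) (2 of 18, 4 adjusted over the list alone, 0.000128, and adjusted p = 0.178 with an estimated correlation). The 9 LXR targets, which respond to sterols, leaned lower with 0 called over all genes and 1 adjusted over the list alone (0.025, and adjusted p = 0.261 with an estimated correlation). Series I moved further than series II in these lists too, with mean changes of 1.40 and 0.96 for ERK feedback, 0.57 and 0.30 for glycolysis, -0.74 and -0.24 for FOXO targets and -0.70 and -0.30 for LXR targets. With the series block interferon genes (0.052 to 0.00241, downward) and stress response genes (0.0709 to 0.0145, upward) were called too, with adjusted p = 0.554 and 0.319 with an estimated correlation. Omitting 1 array gave 21 (0 min I), 67 (0 min II), 42 (60 min I) or 698 genes (60 min II). Nr4a1, Fosl1, Egr1 and Dusp5 kept their calls each time, and 17 of 21 named genes called here lost theirs at least once, Arg1 without 0 min I or 60 min I (adjusted p = 0.0684 and 0.0516).

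At 180 min the changes in WT went both ways, and ribosome biogenesis and cholesterol synthesis genes leaned higher as lists (adjusted p = 0.178 and 0.178 with an estimated correlation). The chemokine gene Ccl2 rose by 3.88 (SE 0.52) and Cxcl2 by 2.69 (SE 0.47), with 2 arrays per group. Met, the receptor of hepatocyte growth factor, rose by 3.05 (SE 0.57), and the Notch ligand gene Jag1 by 2.68 (SE 0.59). The membrane protein gene Tm4sf1 rose by 3.08 (SE 0.49), the ETS factor Etv5 by 2.88 (SE 0.63), Ptgs2 by 3.41 (SE 0.63) and Fosl1 by 3.35 (SE 0.31, adjusted p = 0.00116). Trp53inp1, a p53-induced stress gene, fell to -2.79 (SE 0.46, adjusted p = 0.0179), and Klhl24, Ypel2 and the chemokine receptor gene Cxcr4 fell to -2.60 (SE 0.42), -2.38 (SE 0.40) and -2.13 (SE 0.42). By limma 431 genes changed, 275 up and 156 down, and 1557 with the series block. Of 23 ribosome biogenesis genes 10 rose, led by Odc1 at 2.42 (SE 0.36), Rrs1 at 2.13 (SE 0.49), Nop58 at 1.87 (SE 0.34) and Gnl3 at 1.80 (SE 0.40) (20 adjusted over the list alone, camera adjusted p = 5.21e-21). Of 20 cholesterol synthesis genes 4 rose, Sqle most at 1.74 (SE 0.28) (5 adjusted over the list alone, 7.94e-08), and of 14 ERK feedback genes 7, with Spred2 at 2.46 (SE 0.42) (8 adjusted over the list alone, 6.37e-08, and adjusted p = 0.156 with an estimated correlation). Arg1 stayed up at 2.41 (SE 0.31), 1 of 2 M2 markers that rose (5 adjusted over the list alone, 0.000233), and Tnf, the gene of the inflammatory cytokine TNF, rose by 1.93 (SE 0.41). Ccng2, a cyclin repressed in growing cells, fell to -1.73 (SE 0.37), 1 of the 2 fallen among 18 FOXO targets (7 adjusted over the list alone, 7.67e-05, and adjusted p = 0.178 with an estimated correlation). The M2 list had adjusted p = 0.0475 with an estimated correlation, but 0.0567 with the series block. Omitting 1 array gave 6 (0 min I), 90 (0 min II), 163 (180 min I) or 8 genes (180 min II). Of 24 named genes called at 180 min Fosl1 alone kept its call each time, with Tnf losing its own without 0 min I, 0 min II or 180 min II (adjusted p = 0.294, 0.0621 and 0.299).

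The same times in Y721F asked what a receptor without Tyr-721 still does. At 20 min Egr1 rose by 4.73 (SE 0.30, adjusted p = 6.57e-05), Egr2 by 4.28 (SE 0.66), and the synaptic immediate early gene Arc by 4.08 (SE 0.58). There Nr4a1 rose by 3.33 (SE 0.34), Fos by 2.97 (SE 0.37) and Fosb by 2.91 (SE 0.34), with 2 arrays per group, and these 3, Egr1 and Egr2 had risen in WT too. C030016D13Rik fell to -1.29 (SE 0.18). Ptgs2 measured 3.07 (SE 0.63) and Ccl2 3.29 (SE 0.52) without being called (adjusted p = 0.23 and 0.053, with the series block 0.00242 and 3.25e-05), and Il1b measured 0.79 (SE 0.43, adjusted p = 0.794). At 60 min Egr1 rose by 3.47 (SE 0.30), Nr4a1 by 3.40 (SE 0.34), Ccl2 by 3.06 (SE 0.52), Fosl1 by 3.04 (SE 0.31), Dusp5 by 2.55 (SE 0.35) and Hilpda by 2.47 (SE 0.39). A630072M18Rik, the zinc finger gene Zfp799 and the exchange factor gene Arhgef4 fell to -1.20 (SE 0.19), -1.10 (SE 0.16) and -0.72 (SE 0.11). Of the WT 60 min genes not called in Y721F, Id1 measured 1.47 (SE 0.52), Clec2d -0.85 (SE 0.32) and Prdm1 -0.25 (SE 0.20). Ptgs2, Il10ra and Rgs2 at 2.57 (SE 0.63), -1.26 (SE 0.29) and -0.91 (SE 0.24) were called with the series block (adjusted p = 0.00448, 0.00134 and 0.00964). At 180 min Ccl2 rose by 3.13 (SE 0.52), Fosl1 by 3.12 (SE 0.31) and the ERK phosphatase gene Dusp4 by 2.42 (SE 0.30). Trp53inp1, the kinase gene Tesk2 and Mertk, a receptor for the uptake of dying cells, fell to -2.71 (SE 0.46), -1.70 (SE 0.23) and -1.68 (SE 0.26). Tm4sf1, Met, Etv5, Cxcl2 and Jag1 measured 1.23, 1.78, 2.28, 1.82 and 2.27 (SE 0.49, 0.57, 0.63, 0.47 and 0.59), uncalled, and were called with the series block (adjusted p = 0.0133, 0.0191, 0.00509, 0.0199 and 0.00378). So were Ptgs2 at 2.84, Klhl24 at -2.03, Ypel2 at -1.69 and Cxcr4 at -1.96 (0.00288, 0.00833, 0.0137 and 0.00543). By limma 16 genes changed at 20 min (15 up), 35 at 60 min (32 up) and 52 at 180 min (34 up), and with the series block 49, 170 and 1074.

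At 20 min 10 of 26 immediate early genes rose in Y721F (22 adjusted over the list alone, camera adjusted p = 1.19e-41). At 60 min 6 were still up (19 adjusted over the list alone, 2.17e-39), and 3 of 14 ERK feedback genes rose, Dusp4 at 3.00 (SE 0.30) ahead of Dusp5 and Ets2 (7 adjusted over the list alone, 9.94e-14). At 180 min 3 of 20 cholesterol synthesis genes rose, with the sterol demethylase Cyp51 at 1.80 (SE 0.29) (12 adjusted over the list alone, 2.81e-13, and adjusted p = 0.126 with an estimated correlation). Of 23 ribosome biogenesis genes 0 rose over all genes but 18 adjusted over the list alone (1.54e-16, and adjusted p = 0.219 with an estimated correlation). Cdkn1b, which holds cells in G1, was 1 called FOXO target at -1.23 (SE 0.21) (5 of 18 adjusted over the list alone, 5.7e-06, and adjusted p = 0.128 with an estimated correlation). LXR targets in Y721F were not called at 60 min (camera adjusted p = 0.166) but were lower with the series block (0.0329), and interferon genes went from 0.0535 to 0.00842, higher with the block. With the block these 2 lists had adjusted p = 0.316 and 0.614 with an estimated correlation. At 180 min M2 markers (0.0722), MHC class II genes (0.079), mitotic genes (0.113) and osteoclast markers (0.147) passed with the block (0.033, 0.0354, 0.0104 and 0.0134), the MHC and mitotic lists downward. None of these 4 held with an estimated correlation (with the block, adjusted p = 0.196, 0.546, 0.554 and 0.196). At 20 min in Y721F fibroblast markers leaned higher and macrophage identity genes lower, with 0 of 12 and 0 of 17 called, also adjusted over the list alone (0.0241 and 0.0241, and adjusted p = 0.509 and 0.509 with an estimated correlation). Both come from series I, with mean changes of 0.39 and -0.21 against -0.05 and -0.02 in series II. Egr1 kept its call in Y721F in each omission at 20 and 60 min, as Nr4a1, Fosl1 and Dusp4 did at 60 min. The other named Y721F calls at 20, 60 and 180 min were lost at least once, and Egr2 at 20 min and Ccl2 at 60 min also lost theirs after quantile normalization (adjusted p = 0.0533 and 0.053). Without 1 array the 20 min count was 3 (0 min I), 4 (0 min II) or 3 (20 min I), and the 60 min count 11 (0 min I), 22 (0 min II), 13 (60 min I) or 59 (60 min II). At 180 min it was 86 without 0 min II and 0 without 0 min I, 180 min I or 180 min II, where 1375, 1521 and 2173 genes had an unadjusted limma p under 0.05 and 627, 787 and 1165 passed the cutoff of the series text.

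**Figure D1:**
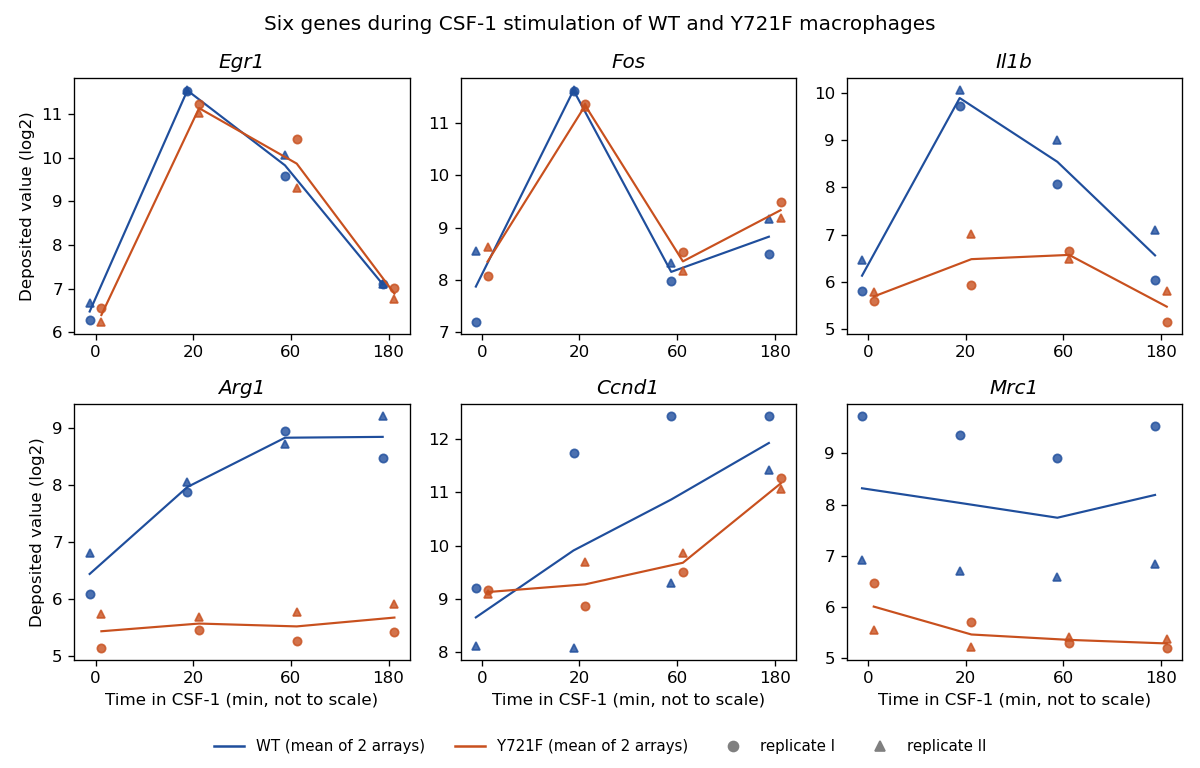
Log2 signal of Egr1, Fos, Il1b, Arg1, Ccnd1 and Mrc1 against minutes of CSF-1, with a point per array (circles series I, triangles series II) and lines through the mean of 2 arrays, WT in blue and Y721F in orange. Egr1 and Fos peak at 20 min in both lines, Il1b and Arg1 rise in WT with the Y721F line below it, and the WT points of Ccnd1 and Mrc1 split by series.

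Whether the response itself differs between the lines with and without Tyr-721 was tested as the difference of the responses of Y721F and WT. Receptor and line are confounded here, and the SE and p read the spread between arrays of the same line. The largest gaps among named genes were in an inflammatory cytokine and in arginase. Il1b rose by 3.76 in WT at 20 min against 0.79 in Y721F, a difference of -2.97 (SE 0.61, adjusted p = 1), and Arg1 by 2.39 at 60 min against 0.08, a difference of -2.31 (SE 0.44, adjusted p = 0.999). At 180 min Arg1 differed by -2.17 (SE 0.44). With the series block, Il1b at 20 min (SE 0.34, adjusted p = 0.0328) and Arg1 at 60 min (SE 0.27, adjusted p = 0.048) were the 1 called gene of their time, and 0 genes at 180 min. Over the other alternatives the adjusted p of Il1b ran from 0.105 to 1 and that of Arg1 from 0.088 to 1. Other WT genes lay closer: Egr1 differed by -0.32 (SE 0.42) at 20 min, Nr4a1 by -1.29 (SE 0.48), Prdm1 at 60 min by 1.22 (SE 0.29) and Tm4sf1 at 180 min by -1.85 (SE 0.69), uncalled. Without the block limma called 0 genes at each of 20, 60 and 180 min, with 810, 640 and 277 genes at an unadjusted p under 0.05 and 144, 139 and 72 past the cutoff of the series text. Of the genes called in WT, 32 of 32, 126 of 126 and 430 of 431 had the same sign in Y721F, where their median change was 0.753, 0.674 and 0.774 of that in WT. Choosing genes by their WT call favours WT, and genes called in Y721F had a median ratio of WT to Y721F of 1.10, 1.09 and 0.950. The 15, 32 and 41 genes called in both lines changed the same way. Among lists, the response of ribosome biogenesis genes was lower in Y721F at 20, 60 and 180 min, with 0 of 23 called, also adjusted over the list alone (camera adjusted p = 0.00479, 9.54e-07 and 0.00949, and adjusted p = 0.58, 0.952 and 0.955 with an estimated correlation). At 20 and 60 min this rests on WT series I, whose ribosome list mean moved by 0.85 and 1.50 against 0.04 and 0.22 in WT series II, 0.25 and 0.42 in Y721F series I and -0.01 and 0.13 in Y721F series II. At 180 min the 4 series moved by 1.37, 1.27, 1.27 and 0.74 in that order, so the lower value there rests on Y721F series II. Glycolysis was lower at 20 and 60 min (0 of 13, also adjusted over the list alone, 0.0118 and 0.00302, and adjusted p = 0.58 and 0.952 with an estimated correlation). At 60 min that too is larger with WT series I, whose glycolysis mean moved by 0.57, than with series II at 0.30 (Y721F 0.23 and 0.11). Immediate early genes (0 of 26) and M1 markers (0 of 19) were lower at 20 min, 0 and 1 adjusted over the list alone (0.0118 and 0.0118, and adjusted p = 0.58 and 0.58 with an estimated correlation). That of M2 markers was lower at 20 min (0 of 23 called singly, 1 adjusted over the list alone, camera adjusted p = 0.00479, and adjusted p = 0.112 with an estimated correlation) and at 180 min (0 of 23, 1 adjusted over the list alone, 0.00949, and adjusted p = 0.143 with an estimated correlation). That of inflammatory genes was lower at 20 min (0 of 24, 2 adjusted over the list alone, 0.00479, and adjusted p = 0.58 with an estimated correlation). The interferon response was higher at 60 and 180 min (0 of 23, also adjusted over the list alone, 0.00175 and 1.71e-06, and adjusted p = 0.952 and 0.955 with an estimated correlation). The inflammatory list rests mostly on WT series I, with mean changes of 1.41 and 0.79 in the WT series and 0.63 and 0.54 in the Y721F series. Cholesterol synthesis was higher at 180 min (0 of 20, also adjusted over the list alone, 0.045, and adjusted p = 0.955 with an estimated correlation). The block added lower stress response genes at 20 min (0.0778 to 0.025), lower glycolysis genes (0.105 to 0.0387) and higher osteoclast markers (0.279 to 0.00909) at 180 min. With an estimated correlation and the block these 3 had adjusted p = 0.549, 0.967 and 0.17. Fibroblast markers leaned higher in the difference at 20 min, with 0 of 12 called, also adjusted over the list alone (0.0199, and adjusted p = 0.58 with an estimated correlation). Interferon genes at 60 min, cholesterol synthesis at 180 min and fibroblast markers at 20 min rest on Y721F series I, with mean changes of 0.51, 1.02 and 0.39 against -0.09, 0.48 and -0.05 in Y721F series II. M2 markers at 180 min moved by 0.18 and 0.22 in the Y721F series against 0.58 and 0.55 in the WT series.

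The starting point of the time course, Y721F against WT at 0 min, asked what already differs in starved cells. Y721F had more Pla2g7 at 4.14 (SE 0.26, adjusted p = 2.85e-05), with 2 arrays per group. Bex3, Nxf7, Sema5a and Sparc were higher too, at 3.47 (SE 0.29), 3.14 (SE 0.28), 3.02 (SE 0.33) and 3.25 (SE 0.59). It had less Lilra5 at -4.32 (SE 0.31, adjusted p = 7.2e-05). Slfn1, Plxdc2, Pygl and Entpd1 (CD39) were lower too, at -5.12 (SE 1.00), -3.67 (SE 0.33), -3.55 (SE 0.36) and -3.47 (SE 0.28). Il1a, the gene of the cytokine IL-1α, was lower at -2.13 (SE 0.42) and the costimulatory gene Cd86 at -1.04 (SE 0.21). By limma 145 genes differed, 84 higher and 61 lower in Y721F. Arrays of a series move together across times, so the fit counts too many independent deviations and these p can be too small. The 23 interferon genes leaned lower, each with a negative difference and 0 called over all genes, and 2 adjusted over the list alone (camera adjusted p = 9.02e-12, and adjusted p = 0.748 with an estimated correlation). Separate arrays of starved cells gave 91 of these genes the same way and 0 the opposite way. There 39 were higher and 52 lower, where independent lists would share 2.92 and 4.67 (exact hypergeometric p = 1.31e-34 and 3.69e-49). Without 1 array the 0 min count was 33 (WT I), 85 (WT II), 52 (Y721F I) or 54 (Y721F II), and Sparc, Slfn1 and Cd86 lost their calls at least once and Il1a in 4 of 4 omissions and after quantile normalization (adjusted p = 0.0544).

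Growth in CSF-1 against starvation, in each of the 4 lines, asked for the lasting effect of the factor. In all 4 lines Ccl7, Ccl2, Ccnd1 and Slc2a1 rose and Clec7a and Mertk fell. Averaged over the lines, the chemokine genes Ccl7 and Ccl2 rose by 3.08 (1.83 to 3.94 per line) and 3.00 (2.45 to 3.50), and Ccnd1, cyclin D1, by 2.69 (2.18 to 3.29), with 2 arrays per group and line. Slc2a1 rose by 2.24 on average, the collagen-modifying Plod2 by 1.98, the urokinase gene Plau by 1.88, Odc1 by 1.87, Etv5 by 1.86, the cytidine deaminase Cda by 1.72 and Sema3c by 1.64. Clec7a, the β-glucan receptor dectin-1, fell to -2.74 on average (-3.63 to -1.51), the selenium carrier gene Selenop to -2.11, Clec4a3 to -2.04, Adgre5 (CD97) to -2.03, Slc46a3 to -2.0 and Mertk to -1.77 (-2.81 to -1.22). Marcks, Wfdc17, Fgl2 and the microsomal transferase Mgst1 fell to -1.68, -1.59, -1.49 and -1.42. Called in the same direction in 4 of 4 lines were 64 genes, 42 up and 22 down. The limma counts per line were 1060 in WT (459 up, 601 down), 985 in Y721F (693 up, 292 down), 282 in 3ABY721 (148 up, 134 down) and 137 in 3AB (86 up, 51 down). After quantile normalization the share of called genes that were up went from 70.4% to 57.8% in Y721F and from 62.8% to 51.5% in 3AB. With 1 array left out, WT gave 412 (starved I), 689 (starved II), 366 (grown I) or 1994 (grown II), and Y721F 229 (starved II). Likewise 3ABY721 gave 64 and 114 (starved I and II) or 95 and 53 (grown I and II), and 3AB 26 and 27 (starved) or 26 and 20 (grown). Of the named genes called in WT, Y721F, 3ABY721 and 3AB, 6 of 25, 5 of 24, 6 of 20 and 17 of 20 lost a call at least once, and in 3AB Ccl7, Clec7a and Slc46a3 kept theirs. There Ccnd1 lost its call in 4 of 4 omissions, Slc2a1 and Ccl2 in 3 and Mertk in 2.

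As lists, ERK feedback and glycolysis leaned higher and macrophage identity lower on growth in each of the 4 lines. ERK feedback and macrophage identity held in WT and 3ABY721 with an estimated correlation, and in Y721F and 3AB ERK feedback had 0.0698 and 0.164 and macrophage identity adjusted p = 0.0698 and 0.165 with an estimated correlation. Glycolysis held in none of WT, Y721F, 3ABY721 and 3AB (adjusted p = 0.285, 0.0939, 0.113 and 0.165 with an estimated correlation). ERK feedback genes rose in 8, 6, 4 and 4 of 14 in WT, Y721F, 3ABY721 and 3AB (9, 6, 8 and 5 adjusted over the list alone; camera adjusted p = 6.46e-10, 3.06e-06, 5.07e-09 and 6.55e-06). Glycolysis genes rose too, 7, 10, 7 and 4 of 13, with Slc2a1 first (8, 10, 9 and 6 adjusted over the list alone; 9.71e-09, 2.03e-12, 5.78e-13 and 5.2e-11). Macrophage identity genes fell, 5, 5, 3 and 1 of 17, Mertk among them (8, 5, 8 and 2 adjusted over the list alone, and 1 up in Y721F; 8.35e-08, 1.67e-07, 5.07e-09 and 8.51e-05). Ribosome biogenesis genes rose in WT (12 of 23, 22 adjusted over the list alone, 1.32e-18, and adjusted p = 0.285 with an estimated correlation). In each other line 1 of 23 rose, also adjusted over the list alone (0.256 in Y721F, 3.71e-09 in 3ABY721 and 1.75e-08 in 3AB, the last 2 with adjusted p = 0.342 and 0.355 with an estimated correlation). In Y721F the stress response rose, with the amino acid enzymes Mthfd2 at 2.27 (SE 0.23) and Asns at 2.06 (SE 0.36) (6 of 16, 10 adjusted over the list alone, 8.7e-09, and adjusted p = 0.0939 with an estimated correlation). Cholesterol synthesis followed (5 of 20, 16 adjusted over the list alone, 2.76e-10, and adjusted p = 0.392 with an estimated correlation). In WT the antigen presentation gene H2-Ab1 fell to -2.52 (SE 0.68), 1 of the 3 fallen among 6 MHC class II genes (6 adjusted over the list alone, 5.25e-05, and adjusted p = 0.331 with an estimated correlation). The sterol exporter Abca1 fell to -2.08 (SE 0.44), 1 of the 3 fallen among 9 LXR targets (4 adjusted over the list alone, 0.0126, and adjusted p = 0.339 with an estimated correlation). In 3AB the 11 dendritic cell markers and 12 fibroblast markers leaned lower with 0 called, also adjusted over the list alone (0.00788 and 0.0039, and adjusted p = 0.165 and 0.234 with an estimated correlation).

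**Figure D2:**
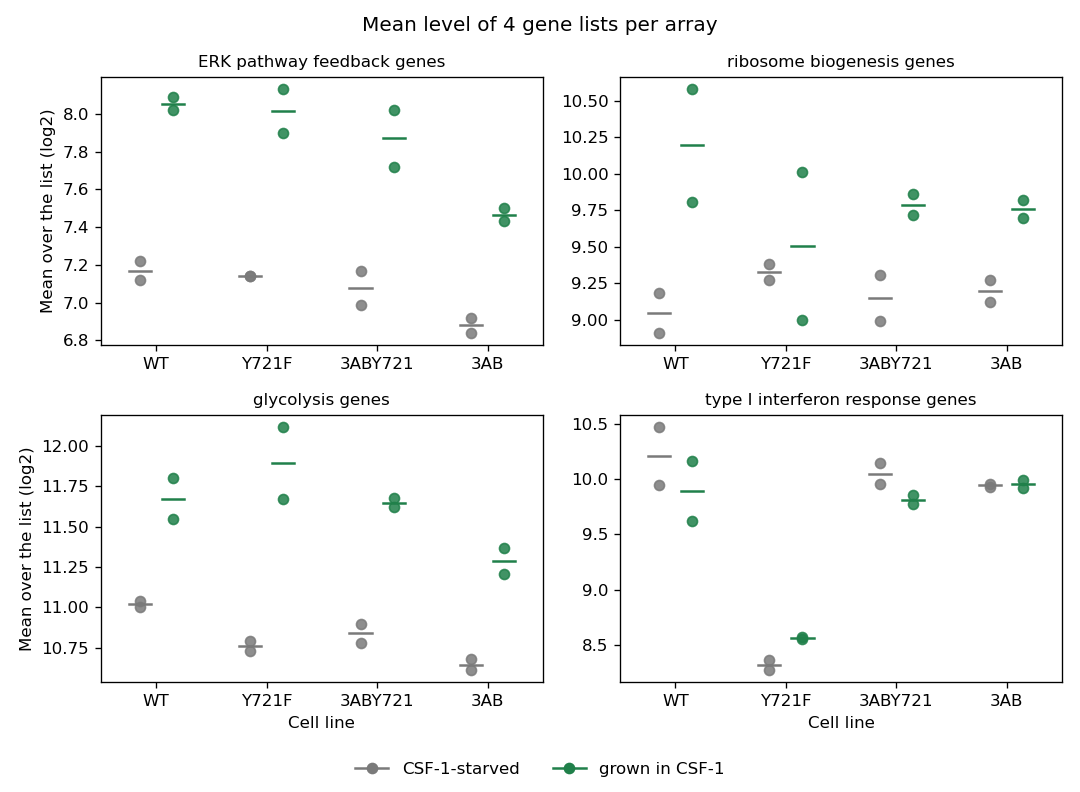
Mean log2 signal of the ERK feedback, ribosome biogenesis, glycolysis and type I interferon lists per array in the 4 lines, grey starved and green grown in CSF-1, with a bar at the mean of 2 arrays. ERK feedback and glycolysis lie higher when grown in each line, ribosome biogenesis separates most in WT (the median change of its Y721F members is 0.13 as deposited and -0.02 after quantile normalization), and interferon genes are lower in Y721F.

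Y721F against WT grown in CSF-1 asked how the line without Tyr-721 differs under continuous factor. Cybb, the core of the phagocyte NADPH oxidase, was lower at -5.87 (SE 0.34, adjusted p = 8.57e-08), the neutrophil collagenase Mmp8 at -5.72 (SE 0.47) and Ms4a6d at -5.16 (SE 0.16), with 2 arrays per group. The steroid enzyme gene Cyp11a1 was higher at 4.67 (SE 0.49), Rgs17 at 3.98 (SE 0.16) and the ubiquitin ligase Nedd4 at 3.86 (SE 0.16). Of 24 inflammatory genes 11 were lower, the chemokines Ccl12, Ccl7 and Cxcl10 at -4.83 (SE 0.46), -3.73 (SE 0.30) and -3.08 (SE 0.37) among them (12 adjusted over the list alone, camera adjusted p = 1.09e-05, and adjusted p = 0.108 with an estimated correlation). Of 23 interferon genes 15 were lower, with the antiviral Ifit3 at -3.44 (SE 0.30) (17 adjusted over the list alone, 1.51e-19, and adjusted p = 0.108 with an estimated correlation). M1 and M2 markers both leaned lower, 7 of 19 M1 markers (7 adjusted over the list alone, 2.7e-05, and adjusted p = 0.108 with an estimated correlation). Of M2 markers 7 of 23 were lower, with Arg1 at -2.59 (SE 0.73) (7 lower and 1 higher adjusted over the list alone, 0.015, and adjusted p = 0.108 with an estimated correlation). Macrophage identity genes were lower in 5 of 17, the IgG receptor Fcgr1 at -5.16 (SE 0.21) (7 adjusted over the list alone, 4.02e-06, and adjusted p = 0.108 with an estimated correlation). By limma 1572 genes differed, 587 higher and 985 lower in Y721F, which is 37.3% higher and 47.8% after quantile normalization. Omitting an array moved that count most for WT I (924), Y721F I (2449) and Y721F II (862), and of 30 named genes called here 8 lost a call at least once, Arg1 without any of these 3 (adjusted p = 0.288, 0.155 and 0.0714).

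Starved, the same pair of lines differed in more genes, interferon genes among them. Of 23 interferon genes 22 were lower in Y721F, Ifit3 at -4.30 (SE 0.30, adjusted p = 5.67e-07), the antiviral enzyme Rsad2 at -3.22 (SE 0.34), Mx1 at -3.12 (SE 0.27) and Oasl2 at -3.06 (SE 0.22), with 2 arrays per group (22 adjusted over the list alone, camera adjusted p = 2.36e-23, and adjusted p = 0.147 with an estimated correlation). Ms4a6c, Ms4a6d and Ms4a6b, membrane proteins of myeloid cells, were lower at -6.67 (SE 0.21), -6.23 (SE 0.16) and -5.65 (SE 0.21) (for Ms4a6c and Ms4a6b a lower bound, as Y721F lay near the background at 4.48 and 4.17), and Pla2g7, Nedd4 and the chaperone gene Clu (clusterin) higher at 3.92 (SE 0.40), 3.57 (SE 0.16) and 2.98 (SE 0.24). Replication genes were lower, 9 of 24 with Mcm10, Chaf1b, Pola1 and Cdc45 ahead (10 adjusted over the list alone, 2.97e-05, and adjusted p = 0.178 with an estimated correlation). Lower too were 5 of 21 mitotic genes (5 adjusted over the list alone, 1.09e-05, and adjusted p = 0.347 with an estimated correlation). So were 4 of 6 MHC class II genes with H2-Aa at -3.84 (SE 0.73) (6 adjusted over the list alone, 0.000205, and adjusted p = 0.299 with an estimated correlation). Osteoclast markers leaned higher, with the fusion protein gene Dcstamp at 2.04 (SE 0.40) and the gelatinase Mmp9 at 1.64 (SE 0.22) but Nfatc1 lower at -0.80 (SE 0.14) (3 of 10 higher, 1 lower, 4 and 1 adjusted over the list alone, 0.0449, and adjusted p = 0.301 with an estimated correlation). Pdgfra, a growth factor receptor of mesenchymal cells, was higher at 1.50 (SE 0.36), 1 of 2 higher among 12 fibroblast markers (3 adjusted over the list alone, 0.0113, and adjusted p = 0.299 with an estimated correlation). Of 14 granulocyte and mast cell markers 0 were called, also adjusted over the list alone, in a list that leaned higher (0.0338, and adjusted p = 0.182 with an estimated correlation). By limma 2219 genes differed, 692 higher and 1527 lower, and after quantile normalization 698 higher and 1001 lower. Without Y721F starved II the count was 1417, and of 27 named genes called here Myc lost its call without WT starved I or Y721F starved I (adjusted p = 0.0551 and 0.0804) and Pdgfra without WT starved II or Y721F starved II. Cdc45 fell below the fold threshold after quantile normalization. In all 3 comparisons of Y721F with WT (0 min, starved and grown, on separate arrays) 76 genes were called the same way.

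The second pair, 3AB against 3ABY721, asked whether the loss of Tyr-721 leaves the same mark in another receptor background. Grown in CSF-1, 3AB had more Ms4a6b, Ms4a7 and the complement gene C1qc, at 3.47 (SE 0.21, adjusted p = 1.54e-06), 3.44 (SE 0.22) and 3.27 (SE 0.72), with 2 arrays per group. It had less Plod2, Clec4n (the fungal receptor dectin-2) and the tubulin gene Tuba8, at -3.11 (SE 0.29), -3.10 (SE 0.32) and -3.01 (SE 0.41). Starved, 3AB had more Ms4a4a, Clec1b and the potassium channel gene Kcnj10, at 3.36 (SE 0.34), 2.83 (SE 0.19) and 2.45 (SE 0.19). It then had less of the opioid precursor Penk, the water channel Aqp8 and Plod2, at -3.21 (SE 0.48), -2.57 (SE 0.21) and -2.53 (SE 0.29). Macrophage identity genes leaned higher in grown 3AB, with Aif1 at 2.08 (SE 0.39), Mertk at 1.41 (SE 0.17) and Fcgr1 at 0.90 (SE 0.21) (3 of 17 higher, 5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00207, and adjusted p = 0.513 with an estimated correlation). Inflammatory genes leaned lower in grown 3AB, 2 of 24 with Cxcl3 at -1.81 (SE 0.36) and Csf2 at -1.08 (SE 0.18) (2 adjusted over the list alone, 0.00226, and adjusted p = 0.513 with an estimated correlation). So did ERK feedback with Dusp4 at -2.67 (SE 0.24) (1 of 14, 2 adjusted over the list alone, 0.0136, and adjusted p = 0.513 with an estimated correlation). By limma 236 genes differed when grown (108 higher, 128 lower in 3AB) and 123 when starved (49 higher, 74 lower). Without 1 array the grown count was 92 or 75 (3ABY721 I or II) and 74 or 83 (3AB I or II), and the starved count 50 or 55 (3ABY721 I or II) and 58 or 38 (3AB I or II). C1qc and Penk lost their calls at least once, as 13 of 26 and 5 of 12 named genes did in the grown and starved comparison, Aif1 and Fcgr1 in 4 of 4 omissions. Fcgr1 also lost its call in grown 3AB after quantile normalization (adjusted p = 0.0547).

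Most genes called in both pairs differed in opposite directions: 90 when grown and 42 when starved, against 21 and 12 the same way. Of the 21, 19 were lower without Tyr-721. In Y721F against WT and 3AB against 3ABY721, Clec4n was lower at -2.52 and -3.10, Aqp8 at -2.59 and -2.78, Cxcl3 at -3.46 and -1.81, with 2 arrays per group and SE between 0.14 and 0.37 for these and the next 7. Tm4sf1 was lower at -2.38 and -2.26 and Glipr2 at -2.28 and -1.83. Cd74, the invariant chain of MHC class II, was lower at -1.99 and -2.12, and Ptgs2 at -2.28 and -1.32. Pcdh7 was lower at -2.25 and -1.31, Ccdc80 at -1.94 and -0.78, and the myeloid receptor Clec5a at -0.93 and -1.51. The iron carrier gene Trf was higher at 1.36 (SE 0.39) and 2.53 (SE 0.39) and the sterol hydroxylase Cyp27a1 at 0.82 (SE 0.24) and 1.21 (SE 0.24). These 21 genes, 2 higher and 19 lower, compare with 3.18 and 6.32 expected of independent lists (exact hypergeometric p = 0.831 and 1.7e-05). Starved, 12 genes were shared, 0 higher and 12 lower, against 1.70 and 5.67 (exact hypergeometric p = 1 and 0.0101), and 6 genes were in both sets. They were led by Aqp8 at -3.45 and -2.57, the detoxifying Ephx1 at -2.02 and -1.97, Glipr2 at -1.98 and -1.51, Prrg4 at -1.63 and -1.73, and Pdlim1 at -1.53 and -1.34 (SE 0.18 to 0.30). Without 1 array the grown set had 33 or 34 genes (WT I or II), 10 or 8 (3ABY721 I or II) and 6 or 7 (3AB I or II), and the starved set 22 (WT I), 4 or 6 (3ABY721) and 6 or 6 (3AB). When grown, Clec4n, Aqp8, Tm4sf1 and Glipr2 kept their calls in both pairs each time, and Cxcl3, Cyp27a1, Cd74, Ptgs2, Pcdh7, Ccdc80, Clec5a and Trf lost one at least once. Starved, Aqp8 and Glipr2 kept theirs, and in 3AB against 3ABY721 Prrg4 lost its call in 4 of 4 omissions, Pdlim1 in 3 and Ephx1 in 2.

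**Figure D3:**
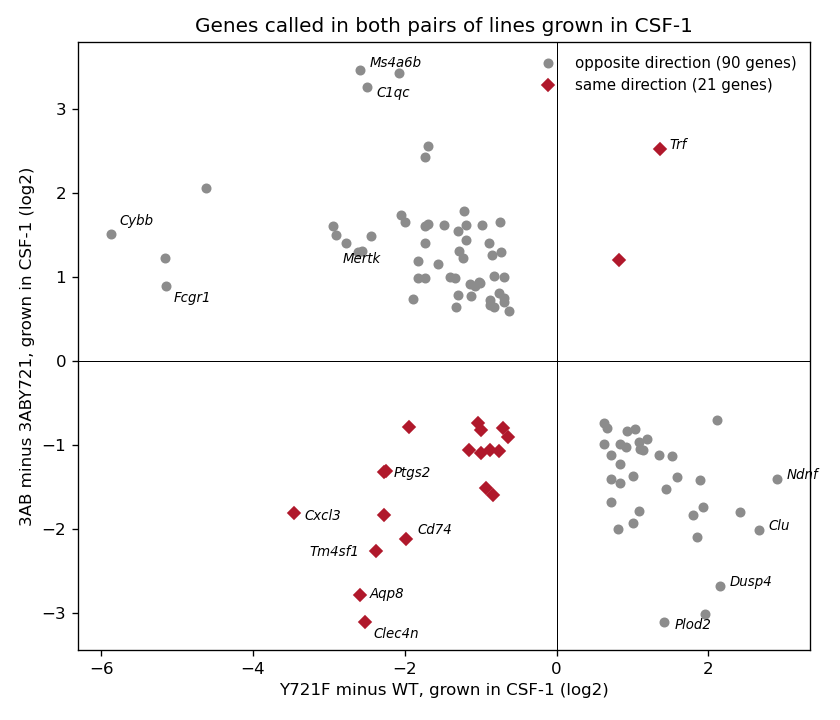
Log2 difference of Y721F against WT (horizontal) and of 3AB against 3ABY721 (vertical), both grown in CSF-1, with a point per gene called in both pairs, red for the 21 with the same direction and grey for the 90 with opposite directions. Red points such as Clec4n, Aqp8 and Tm4sf1 lie in the lower left, and more grey points lie where Y721F is lower and 3AB higher (55) than the reverse (35).

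Whether growth in CSF-1 acts differently in the lines without Tyr-721 was tested over both pairs at once. By limma 6 genes differed, 5 with a higher growth effect in the lines without Tyr-721 and 1 with a lower one. Ms4a6b fell on growth in CSF-1 by 2.84 in WT and measured 0.22 in Y721F, -2.42 in 3ABY721 and -0.82 in 3AB, a difference averaged over the pairs of 2.33 (SE 0.21, adjusted p = 0.000485). The transcript AW112010 at 1.88 (SE 0.19), Ms4a7 at 1.67 (SE 0.22), Ms4a6c at 1.41 (SE 0.21) and the G-protein regulator Rgs17 at 1.25 (SE 0.16) were the other 4 higher ones. Rgs17 gave 2.55 in the pair of Y721F and WT and -0.06 in the pair of 3AB and 3ABY721, so its call rests on 1 pair. In 3AB and 3ABY721 Rgs17 lay near the background (percentiles 19.3 to 22.0), where a fall could not be read. AW112010 and the 3 Ms4a genes lay near the background in starved Y721F, at log2 levels from 4.17 to 4.88 (percentiles 8.05 to 17.9). A fall could not be read there. In the pair of 3AB and 3ABY721 their growth effects differed by 1.34 (AW112010), 1.60 (Ms4a6b), 1.31 (Ms4a7, a lower bound) and 0.77 (Ms4a6c). Tm4sf1, which gained 2.14 in WT and 1.95 in 3ABY721 against 0.85 in Y721F and 0.34 in 3AB, differed by -1.45 (SE 0.14, adjusted p = 0.000485). As lists, ribosome biogenesis lay lower in this difference (0 of 23 called singly, also adjusted over the list alone, camera adjusted p = 6.59e-10) and interferon genes higher (0 of 23, also adjusted over the list alone, 2.95e-08), with adjusted p = 0.632 and 0.632 with an estimated correlation. The ribosome list rests on the pair of Y721F and WT: its median change on growth was 1.135 in WT and 0.125 in Y721F, but 0.605 in 3ABY721 and 0.535 in 3AB. The interferon list rests mostly on that pair too, with medians of -0.37 in WT, 0.275 in Y721F, -0.185 in 3ABY721 and -0.015 in 3AB. At an unadjusted limma p under 0.05 there were 1511 genes. In 1 fit of 32 arrays limma called 0, with 1550 at an unadjusted p under 0.05 and 210 past the cutoff of the series text. The count was 45 without WT grown II and 27 without Y721F grown I, Ms4a6c lost its call in 9 of 16 omissions and Ms4a7 in 1, and the other 4 genes kept theirs.

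The series asks about microRNA-21, and its reported targets gave a mixed picture. Pdcd4, a translation inhibitor and classic miR-21 target, fell in WT grown in CSF-1 at -1.34 (SE 0.26, adjusted p = 0.00796) with 2 arrays per group. It measured -0.21 (SE 0.26) in Y721F, -0.84 (SE 0.26) in 3ABY721 and -0.52 (SE 0.26) in 3AB. That call was lost without WT starved I or WT grown I (adjusted p = 0.0973 and 0.0793), and the growth effect on Pdcd4 over both pairs differed by 0.73 (SE 0.26, adjusted p = 0.643). After 180 min of CSF-1 Pdcd4 measured -2.10 (SE 0.52) in WT and -1.30 (SE 0.52) in Y721F, uncalled (adjusted p = 0.0584 and 0.296) but called with the series block (0.00477 and 0.0494). Other reported targets went up: Rhob by 3.02 (SE 0.22) and Btg2 by 2.67 (SE 0.37) in WT at 20 min (2 of 19, 2 adjusted over the list alone, camera adjusted p = 0.000131). Jag1, Rhob, Map2k3 and Tpm1 followed at 180 min (5 up and 2 down adjusted over the list alone, 0.0683). In Y721F the list was called upward at 20, 60 and 180 min (2, 1 and 0 of 19 rose, 2, 3 and 4 adjusted over the list alone with 1 down at 180 min, 0.0155, 0.000384 and 0.0305). With an estimated correlation these had adjusted p = 0.163, 0.0231 (0.0519 with the series block) and 0.128. The difference of responses of this list was not called at any time (camera adjusted p = 0.596, 0.662 and 0.945). In WT at 60 min the median of the list was -0.05, its mean 0.30 and its test upward (0.0913). In each list called by camera in any comparison, median, mean and test had the same sign. Btg2 is also 1 of the immediate early genes, and Marcks fell on growth in each line as given above. Spry2, an ERK brake and reported target, was higher in Y721F grown in CSF-1 than in WT at 1.35 (SE 0.26, adjusted p = 0.00389) and rose there on growth at 0.93 (SE 0.26). Both calls were lost without Y721F grown II (adjusted p = 0.0594 and 0.271), among other omissions. At 60 and 180 min in Y721F it measured 0.84 (SE 0.20) and 0.69 (SE 0.20), called with the series block (adjusted p = 0.0401 and 0.0253). Spry1 was not called in any comparison, with differences between -0.30 and 0.46.

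Macrophage activation markers were read in every comparison. Growth in CSF-1 lowered the mannose receptor gene Mrc1 in WT at -1.13 (SE 0.23, adjusted p = 0.011) and raised it in Y721F at 1.28 (SE 0.23, adjusted p = 0.00523). Mrc1 was lower in Y721F than WT, starved at -3.26 (SE 0.23) and grown at -0.85 (SE 0.23), but higher in 3AB than 3ABY721, at 1.82 (SE 0.23) and 1.27 (SE 0.23). Its growth effect over both pairs differed by 0.93 (SE 0.23, adjusted p = 0.583), and its lower value in grown Y721F lost the call after quantile normalization (adjusted p = 0.0547). The Mrc1 calls in starved cells held in each omission and that of grown 3AB in none of 4 (adjusted p = 0.051 to 0.18). That of WT growth was lost without WT starved I or grown I (0.123 and 0.118) and that of Y721F growth without Y721F starved II or grown II (0.0861 and 0.0555). Lower Mrc1 in grown Y721F was not called without WT II or Y721F I (0.149 and 0.177). Arg1 rose in WT grown in CSF-1 at 2.91 (SE 0.73, adjusted p = 0.0317), not without WT starved II or grown I (adjusted p = 0.223 and 0.278), and measured 1.11 (SE 0.73), 1.89 (SE 0.73) and 1.48 (SE 0.73) in Y721F, 3ABY721 and 3AB, uncalled. Cd86 was lower in Y721F than WT, grown at -2.55 (SE 0.25, adjusted p = 1.23e-05) and starved at -1.92 (SE 0.25). So was Myc, a proliferation factor, at -1.64 (SE 0.45, not called without WT grown I or Y721F grown I) and -1.93 (SE 0.45). Tnf was lower in grown Y721F at -1.41 (SE 0.30, adjusted p = 0.00762), not without Y721F grown II (adjusted p = 0.0764). After CSF-1 Tnf measured 1.57 (SE 0.41) at 20 min and 1.67 (SE 0.41) at 60 min in WT, and 1.33 (SE 0.41) at 60 min and 1.82 (SE 0.41) at 180 min in Y721F, called with the series block (adjusted p = 0.0232, 0.00457, 0.0398 and 0.00471). Il10 was higher in starved 3AB than 3ABY721 at 0.73 (SE 0.15, adjusted p = 0.0484), a call lost after quantile normalization (adjusted p = 0.0649) and in each omission. At 60 min Il10 measured 1.55 (SE 0.44) in WT and 1.59 (SE 0.44) in Y721F (series block 0.0155 and 0.0359). Ccnd1 measured 3.27 (SE 1.07) in WT and 2.04 (SE 1.07) in Y721F at 180 min, and 2.21 (SE 1.07) in WT at 60 min, uncalled (series block 0.00319, 0.0332 and 0.0341). Myc measured 1.36, 1.94 and 2.03 in WT and 1.76, 2.98 and 2.18 in Y721F at 20, 60 and 180 min (SE 0.64), uncalled (series block 0.0306, 0.00082, 0.000815, 0.00606, 9.91e-05 and 0.00131). Fos at 180 min measured 0.95 (SE 0.37) in WT and 0.98 (SE 0.37) in Y721F and Arg1 at 20 min in WT 1.53 (SE 0.31), uncalled (series block 0.0363, 0.0408 and 0.00224). Outside the growth difference, 12 of 283 called results of named genes had a group under the 20th percentile, so their size is a lower bound. These are Ms4a6c, Ms4a6b and Mx1 in starved Y721F, Clec4n and Ms4a6c in grown Y721F, Ms4a7 and Csf2 in the grown and Penk and Il10 in the starved pair of 3AB and 3ABY721, Nxf7 at 0 min, Met in WT at 180 min and C030016D13Rik in Y721F at 20 min. Il6, Nos2, Il12b and Cd163 were not called in any of the 19 comparisons by limma. The 10 lymphocyte markers had 0 called members in any comparison, also adjusted over the list alone, with camera adjusted p from 0.141 upward. Of 163 list calls at the preset correlation, 14 held with an estimated one, each in the same direction. These were immediate early genes in WT and Y721F at 20 min and Y721F at 60 min, and inflammatory genes, M1 markers and miR-21 targets in WT at 20 min. The others were M2 markers in WT at 20 and 180 min, ERK feedback and miR-21 targets in Y721F at 60 min, and ERK feedback and macrophage identity in grown WT and 3ABY721. With the series block in the time course, M2 markers in WT at 180 min and miR-21 targets in Y721F at 60 min no longer held, and ERK feedback in WT at 20 min did.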

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

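In this part the tests of the opposite pairs by label exchange and by quantile normalization were fixed before their results were seen, and the test on starved cells, the correlation over further gene sets and the look at background levels were chosen after the result was seen.

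A difference between groups of lines flagged 6 genes: the effect of growth in CSF-1, tested as its own contrast by limma, differed between the lines without Tyr-721 and those with it. Ms4a6b differed by 2.33 (SE 0.21, adjusted p = 0.000485), AW112010 by 1.88 (SE 0.19, adjusted p = 0.000485), Ms4a7 by 1.67 (SE 0.22, adjusted p = 0.00927) and Ms4a6c by 1.41 (SE 0.21, adjusted p = 0.023). Growth lowered these 4 genes in WT and 3ABY721, at -2.84 and -2.42 for Ms4a6b, -2.80 and -2.89 for AW112010, -2.40 and -1.89 for Ms4a7 and -1.88 and -1.71 for Ms4a6c. In Y721F and 3AB the values were 0.22 and -0.82, -0.38 and -1.55, -0.36 and -0.59, and 0.18 and -0.94. Starved Y721F lay near the background in these genes (percentiles 8.05 to 17.9), which left no room for a fall. The pair of 3AB and 3ABY721 can be read, at 1.60, 1.34, 1.31 and 0.77, but was not tested alone. The 1.31 of Ms4a7 is a lower bound (grown 3ABY721 at percentile 19.9). Tm4sf1 differed by -1.45 (SE 0.14, adjusted p = 0.000485) and Rgs17 by 1.25 (SE 0.16, adjusted p = 0.00927). For Rgs17 the pair of Y721F and WT gave 2.55 and the other pair -0.06, so its call rests on 1 pair. The 3 Ms4a genes lie in a cluster of related genes, and whether their probes read one another was not tested. In 1 fit of 32 arrays 0 genes were called, with 1550 at an unadjusted limma p under 0.05 and 210 past the cutoff of the series text.

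The pattern weighed here is that the same loss of Tyr-721 went with opposite differences in the pairs of lines: grown in CSF-1, 90 genes were called in opposite directions, against 9.10 expected of independent lists, and 21 in the same direction; 55 of the 90 were lower in Y721F and higher in 3AB, such as Cybb (-5.87 and 1.52), Ms4a6d (-5.16 and 1.23) and Ms4a6c (-4.62 and 2.06), where Cybb lost its call in 3AB in 4 of 4 omissions and after quantile normalization (adjusted p = 0.0832), and 42 genes were opposite when starved (6.32 expected). Exchanged labels of 3AB and 3ABY721 are argued against only over genes called in WT at 180 min or on growth in WT or Y721F, assuming that the loss acts alike in both pairs. An exchange needs a negative correlation across genes of the difference of responses at 180 min (Y721F minus WT) with that of growth effects (3AB minus 3ABY721). Over 431 genes called in WT at 180 min r was 0.3635 (95% bootstrap interval 0.223 to 0.491, Spearman 0.332). It was 0.204 to 0.349 over 16 choices of single 3AB and 3ABY721 arrays, but 0.0489 to 0.379 over those of single time-course arrays. Choosing genes by that WT call favours WT and genes are not independent, but over 1060 genes called in WT growth, whose arrays enter neither difference, r was 0.3462 (0.2605 to 0.4294, 0.0275 to 0.374 over single time-course arrays), against 0.1999 (0.000257 to 0.313 over those arrays) over 985 called in Y721F growth, -0.0273 (-0.298 to 0.357) over 52 called in Y721F at 180 min and 0.0400 over all genes, where r took both signs over single 3AB and 3ABY721 arrays (-0.153 to 0.108 and -0.0834 to 0.153) and time-course arrays (-0.19 to 0.205 and -0.0363 to 0.0815). The WT growth set is again chosen by a call in WT, and the genes called in Y721F at 180 min and all genes do not decide the exchange. Remaining differences in the distribution of the deposited values are argued against by the 79 opposite genes after quantile normalization (7.75 expected). An effect of the normalization before deposit was not tested. Line differences that do not need CSF-1, such as clonal origin, stay open. Starved, 0.9778 of the genes (88 of 90, interval 0.922 to 0.997) kept both directions. CSF-1 effects could outlast starvation, so this share does not decide between them. Receptor background, confounded with clone, was not separated.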

How the results depend on the processing

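In this part the alternatives with the series number within each line as a block, (in the time course and on growth), with 1 WT series alone and with crossed numbers were chosen after seeing the data. Counts are genes called by limma, with comparisons in a fixed order: WT at 20, 60 and 180 min, then Y721F at 20, 60 and 180 min; "growth" is grown in CSF-1 against starved.

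The counts depend mostly on the cutoff and on which arrays give the spread, and less on normalization. With 2 arrays per group the number of arrays limits what can be called, a gene near the array background reads compressed changes, and the normalization before deposit cannot be undone. Quantile normalization and leaving out dim genes kept each total count within 1.5 times its value. By direction, after quantile normalization the lower genes of Y721F vs WT starved went from 1527 to 1001 and the 1 lower gene of WT at 20 min to 0. No named result that was called in the main fit or under the alternative turned direction. Directions of results uncalled in both fits were not compared. Of the named results, quantile normalization kept 635 and ended 9 calls, and the leave-one-out refits kept 2768, ended 417 and added 11. Kept results include those uncalled in both fits, so the kept counts do not give the share of calls that held. All probe sets ended 76 calls and added none to the named genes. The 1 fit of 32 arrays ended 65 and added 17, and trend and robust variance ended 23. Leaving out dim genes added 2 among the named genes it still tested, and the cutoff of the series text added 63.

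With the cutoff of the series text (fold above 1.5, unadjusted p under 0.05), by construction looser, the 6 time-course counts were 148, 826, 1415, 128, 307 and 1050, the response differences 144, 139 and 72, Y721F vs WT at 0 min 704, growth in WT 1652, 3ABY721 823 and 3AB 618, 3AB vs 3ABY721 614 grown and 465 starved, the growth difference 252, and both pairs 72 grown and 59 starved. With all probe sets, which means more tests, WT at 180 min gave 134, Y721F 7, 23 and 4, growth in 3ABY721 168 and 3AB 49, 3AB vs 3ABY721 starved 70, the growth difference 3 and both pairs starved 5. In 1 fit of 32 arrays, where both experiments share 1 spread, the 6 time-course counts were 50, 202, 809, 27, 65 and 359, Y721F vs WT at 0 min 275, growth in WT 691, 3ABY721 152 and 3AB 53, 3AB vs 3ABY721 grown 148, both pairs grown 11 and the growth difference 0 (unadjusted limma p under 0.05: 1550; cutoff of the series text: 210); the response differences stayed 0 (unadjusted p under 0.05: 577, 499 and 198; cutoff of the series text: 147, 171 and 76); the cause was not tested. Trend and robust variance left 33 for Y721F at 180 min; the cause was not tested.

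The replicate number as 1 block over both lines gave 259 for WT at 60 min, 932 at 180 min, 79 and 453 for Y721F at 60 and 180 min and 400 for Y721F vs WT at 0 min. The series number within each line as a block gave 86, 745, 1557, 49, 170 and 1074 for the 6 time-course counts and 1, 1 and 0 for the response differences, added 38 calls and ended none among named genes, and took the list calls of the time course from 74 to 85 with 74 kept. The block lowers the spread because arrays of 1 series move together; Y721F vs WT at 0 min lies between these blocks and was not refitted with them. In the steady-state experiment same-numbered starved and grown arrays of 1 line correlated at 0.2553 in WT, 0.1198 in Y721F, 0.2798 in 3ABY721 and 0.0423 in 3AB, and arrays of different lines between -0.328 and 0.283, so the numbers were not taken as pairs because 3AB stayed below 0.1. The number within each line as a block gave 1333, 1134, 429 and 222 for growth in WT, Y721F, 3ABY721 and 3AB and 9 for the growth difference. The replicate number as 1 block over the lines gave 1185, 1006, 286 and 137 for growth in WT, Y721F, 3ABY721 and 3AB, 1625 and 2250 for Y721F vs WT grown and starved, 256 and 143 for 3AB vs 3ABY721, 7 for the growth difference, and 23 and 15 for both pairs; 1 named call was lost (Wfdc17 in growth of 3AB, adjusted p = 0.052). Crossing the numbers of the starved 3AB arrays gave 143 for 3AB vs 3ABY721 starved. Beyond those given beside results, the block changed no other call of a named gene in the time course.

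WT series I alone gave 20, 344 and 97 for WT, 305 for Y721F vs WT at 0 min and 1 for the response difference at 60 min; series II alone gave 8, 13 and 67, and 67 at 0 min; these have fewer arrays. With series I alone 26 named calls were lost, among them Egr2 at 20 min (adjusted p = 0.549) and Ccl2 at 20 min (0.114), and with series II alone 45; Ccnd1 at 180 min was called with each alone (0.0135 and 0.0171). Leaving out 1 array, so with fewer arrays, gave 12 to 20, 21 to 698, 6 to 163, 3 to 13, 11 to 59 and 0 to 86 for the 6 time-course counts and 33 to 85 for 0 min. The response differences stayed 0 in 8 omissions each (unadjusted limma p under 0.05: 296 to 2096, 375 to 1732 and 216 to 451; cutoff of the series text: 60 to 889, 115 to 1085 and 80 to 187). Growth gave 366 to 1994 in WT, 229 to 1230 in Y721F, 53 to 114 in 3ABY721 and 20 to 27 in 3AB, Y721F vs WT 862 to 2449 grown and 1417 to 2092 starved, 3AB vs 3ABY721 74 to 92 and 38 to 58, the growth difference 4 to 45, and both pairs 6 to 34 grown and 4 to 22 starved. The 0 of Y721F at 180 min came with 1375, 1521 and 2173 genes at an unadjusted p under 0.05.

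With an estimated correlation 14 of 163 list calls held, with the replicate block 170 lists were called (163 kept) and with dim genes left out 153 (149 kept). The share of higher genes moved by over 10 points after quantile normalization for growth in Y721F and 3AB and for Y721F vs WT grown; the cause was not tested.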

Other observations

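In this part the tests of the WT series, by mixing with Y721F, by quantile normalization, by the time label and by the genes moving in Y721F, were chosen after the results were seen.

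The 2 WT series of the time course stand apart at every time. At each of 0, 20, 60 and 180 min 59 genes were over 2-fold lower in WT series II than in series I and 29 over 2-fold higher, against 26 and 30 in Y721F; the genes named here were chosen after their values were seen. Averaged over the 4 times with 1 array per series and time, Folr2 lay at -3.39, Mrc1 at -2.62 and Mmp12 at -2.51. C1qc and C1qb lay at -2.60 and -2.44, Ccnd1 at -2.22 and Mx1 at -2.21. Gprc5c lay higher in series II at 2.80, Ndrg2 at 2.47, Bmpr1a at 2.20 and Ace at 2.08. By fixed list, averaged likewise and untested, 21 of 23 interferon genes lay lower in WT series II (mean -0.61). So did 18 of 24 inflammatory (-0.43), 22 of 23 ribosome biogenesis (-0.34) and 12 of 14 ERK feedback genes (-0.34). Higher in series II were NF-κB feedback (0.30, 3 of 15 lower) and LXR targets (0.27, 3 of 9). So were immediate early genes (0.22, 3 of 26) and MHC class II (0.18, 1 of 6). Inflammatory, ribosome, ERK feedback and MHC class II lists moved more in series I at 20 and 60 min. Their means do not show a split at every time. Of the macrophage identity list 11 of 17 lay lower (-0.30) and of M2 markers 8 of 23 (-0.10). In Y721F the interferon list also lay lower in series II (mean -0.37), while the inflammatory, ribosome biogenesis, ERK feedback, macrophage identity and M2 lists had means of -0.15, 0.21, -0.10, 0.03 and 0.02.

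The first pattern weighed here is this split of WT. Y721F cells or RNA in series II are argued against at the share that genes 4-fold lower in Y721F ask for, 65.1% from 54 genes. That share predicts a median rise of 2.14 for 9 genes 4-fold higher in Y721F. The observed median was 0.3 (quartiles 0.145 to 0.8125), a gap beyond the quartile spread of 1.17. The 54 genes were chosen partly by their level in series I, which can raise that share, so a smaller admixture is not argued against. Remaining differences in the distribution of the deposited values are argued against by the correlations across genes of the series difference between times. After quantile normalization these stayed between 0.4845 and 0.743 over 6 pairs of times. An effect of the normalization before deposit was not tested. A difference between separate cultures, such as their state before starvation, stays open and was not tested, since the series number confounds culture with everything else that was done once per series.

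The next pattern is that the WT series I array at 60 min ran ahead of series II: without the 60 min array of series II, 698 genes were called in WT at 60 min, and without that of series I 42. Ribosome biogenesis genes of the series I array lay at a median position of 1.03 on the way from the 60 to the 180 min level of series II (20 genes), where 1 is the 180 min level. A wrong time label or a harvest near 180 min is argued against, since falling immediate early genes of the same array lay at 0.3772 (quartiles 0.163 to 0.5558, 8 genes) and so had not reached their 180 min level. A harvest somewhat later than 60 min stays open for that array. There 64 genes that fell over 2-fold from 60 to 180 min in Y721F lay lower than in series II by a median of -0.5933 beyond the series difference at the other times (quartiles -0.9933 to -0.3217), and 38 that rose lay higher by 0.9717. A late harvest at 60 min would not account for the lead of series I in some lists at 20 min. There ribosome biogenesis moved by 0.85 in series I and 0.04 in series II, and ERK feedback by 0.95 and 0.42. Immediate early genes moved alike at 20 min, by 1.98 and 1.98. A faster or stronger response in series I stays open too, as it predicts the same values at 60 min and was not tested apart.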
